A study of Danio rerio with 6 samples.

How the data were processed

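Gene expression was measured by RNA sequencing in heads of zebrafish (Danio rerio) embryos at 2 days post fertilization. The series holds 6 libraries in 2 groups: 3 from slbp1 −/− mutants of the allele named in the titles and 3 from their wildtype siblings. Group and replicate number of each library came from its title and genotype label. The labels do not say whether the libraries came from separate clutches or pools of heads, so the p-values measure only the spread between these libraries, which may be technical.

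The authors deposited raw whole-number counts per Ensembl gene, in 1 table with a column per library. HISAT2 and featureCounts are named as tools and GRCz11 as the genome build, per the submitters' processing notes, with no version. The annotation release, the strand setting, the treatment of reads that map to several genes, and any selection of polyadenylated RNA are not given in the sources used here. Near-identical copies, above all the clustered histone genes, may therefore have gained or lost reads to each other, and reads of overlapping genes on opposite strands cannot be told apart. Values of single histone genes are uncertain for this reason, and the summed value of the list is given beside them.

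The table had 32520 genes, of which 8047 had no count in any library. A reference table gave a symbol for 29201 of them (89.8%), which carried 98.7% of the counts. It mixes zebrafish symbols with upper-case symbols shared by both zebrafish copies of a gene, so the Ensembl identifier is printed where copies need to be told apart. No genome of the build used by the authors was at hand. The RefSeq gene table of another assembly, GRCz12tu, served only for the order of genes, and 17144 genes were matched to it.

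Counts summed to between 3421961 and 5395071 per library. At this depth 3 counts, taken per library as the floor, correspond to a mean of 0.616 CPM (counts scaled to a common library total) in siblings and 0.696 CPM in mutants. These floors cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom between replicates ran from 6.34 to 17.6.

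Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, libraries were scaled by TMM factors from 0.788 to 1.14, and the 2 groups were compared with edgeR's quasi-likelihood test (robust, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are mutant minus sibling, and CPM values use the TMM-scaled library sizes. For a gene with no count in 1 group, the fold is given as a lower bound against the floor of 3 counts per library.

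The gene lists were fixed before the data were examined, and 948 of 1007 members were matched to a gene in the table. A member found only under a shared upper-case symbol brought in every gene with that symbol. Lists can therefore hold copies that were not on the fixed list, such as 60 genes for 49 matched photoreceptor members. A list with tested members was compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over 30 lists. Camera with the correlation estimated per list, and fry, which tests whether genes of a list move one way on balance, were run beside it. The posterior trunk list had no tested member. Replication-dependent histone genes were taken by symbol, since neither coding sequences nor gene descriptions were at hand. This symbol pattern also took in h2ax2, an H2A.X gene by its name.

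Genes named in the text were chosen by a rule fixed before the data were examined. It takes slbp and slbp2, then the 12 highest and 12 lowest genes by log2 fold change among called genes with an average log2 CPM of 1 or more, non-overlapping groups and a symbol that is not an automatic or clone name. It adds up to 4 called members of each list by lowest p. Some genes that it takes are not reported here. Genes named outside it are marked as chosen after their values were seen. The exceptions are genes of the germ plasm list and of the piRNA and meiosis list, which the closing section names outside the rule without a mark.

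The procedure was tested on simulated data made from the means and sizes of these libraries. Over 14968 genes, 44% of 100 genes changed 2-fold and 85% of 100 genes changed 4-fold were recovered, and 14 of 143 calls were false. Only these 200 genes and a list of 30 were changed, while 25.7% of tested genes were called in the real data. The rates may therefore not carry over to the real comparison. None of 30 unchanged lists was called (0 calls), and a list of 30 genes raised 1.5-fold had an adjusted p of 1.87e-11 by camera. Genes were simulated independently of each other, so this does not check camera where genes of a list move together. In the real data the estimated correlation within a list reached 0.719.

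Alternatives were other size factors (RLE, upper quartile, total counts alone), no low-count filter or 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each library left out, and the replicate number as a block. Further ones were a threshold of 0.01, edgeR's glmTreat against a fold of 1.5, and removal of abundant lists. Figures were drawn with matplotlib 3.10.9.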

Results

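Heads of slbp1 mutant zebrafish embryos and of their wildtype siblings were compared at 2 days post fertilization to find which transcripts differ when slbp1 is mutated. The gene, annotated as slbp, encodes the protein that binds the stem-loop at the 3' end of replication-dependent histone mRNA. Each group had 3 libraries. Total counts were 4525049, 4419886 and 5395071 in mutant replicates 1 to 3, and 3421961, 5258641 and 5155592 in the siblings.

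The slbp transcript (ENSDARG00000100558) was present in every mutant library and 1.75-fold higher than in siblings. It had 169 ± 21.5 CPM in mutants and 96.6 ± 8.67 CPM in siblings (SD, n = 3), with a log2 fold change of 0.81 ± 0.16 (SE) and an adjusted p of 0.00295 by edgeR's quasi-likelihood test. The labels do not describe the lesion, so this level does not check the genotypes. The related slbp2 (ENSDARG00000069428) had 1 count in 1 sibling library and 0 in the other libraries.

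Mutant and sibling heads differed in many genes, in both directions. Of 15561 genes tested with edgeR's quasi-likelihood test, 4004 (25.7%) were called, 2015 higher and 1989 lower in mutants. At least 2-fold differences were seen for 1081 higher and 1381 lower genes, and at least 8-fold differences for 212 and 112. The 3 mutant libraries lay wholly on one side of the siblings for 6783 genes (43.6%, against 10% by chance). The first principal component held 69.4% of the variance and separated the groups. Mutant replicate 3 stood apart from the other mutants, at -43.2 on the second component against 23.6 and 34.3, and had the lowest TMM factor, 0.788; without it 3401 genes were called. Scaling by total counts alone moved the median log2 change of all genes to -0.26 and gave 1095 higher and 2787 lower calls, so that 28.2% of calls were higher against 50.3%. Without sibling replicate 1, 2521 genes were called.

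Among the 12 highest genes by the naming rule, which leaves out clone and automatic names, 9 were histone genes. The rule ranks by fitted log2 fold change, also for genes with no count in siblings, so the bounds below would order them differently. hist1h2a2, h2bc1 and hist1h2a4 had no count in any sibling library and were at least 47.0-fold, 26.3-fold and 13.6-fold higher in mutants. hist1h2a7 had 338 ± 125 CPM in mutants and 0.628 ± 0.434 in siblings (SD, n = 3), and histh1l3, a linker histone by its name, had 417 ± 235 against 0.998 ± 0.521. The others were the globin genes HBE1 and hbaa1 and the MHC class I gene mhc1zfa, which was at least 8.62-fold higher. The globin values varied widely, with HBE1 at 4.63, 33.3 and 5.90 CPM and hbaa1 at 2.32, 49.0 and 14.2 CPM in the mutant libraries. The call on HBE1 was lost without mutant replicate 3 or without any 1 sibling library, at adjusted p from 0.0587 to 0.226 by edgeR's quasi-likelihood test, and hbaa1 likewise at 0.0967 to 0.165. Both were also lost without a low-count filter (0.203 and 0.0821).

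The lowest genes included six7 and CKMT2 of the photoreceptor list. The transcription factor six7 fell from 103 ± 9.33 to 2.01 ± 1.67 CPM (SD, n = 3). SAMD7, which is not on that list, fell from 71.8 ± 17.6 to 1.24 ± 1.14 CPM. prr35, foxq2 and myl13 had no count in any mutant library and were at least 18.4-fold, 17.4-fold and 10.3-fold lower. opn6a, arl3l1, CKMT2, RASGRF2, KCTD20 and MYL11, a muscle myosin light chain, were also among the 12 lowest, with sibling means between 12.6 and 38.5 CPM and mutant means under 1 CPM.

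**Figure D1:**
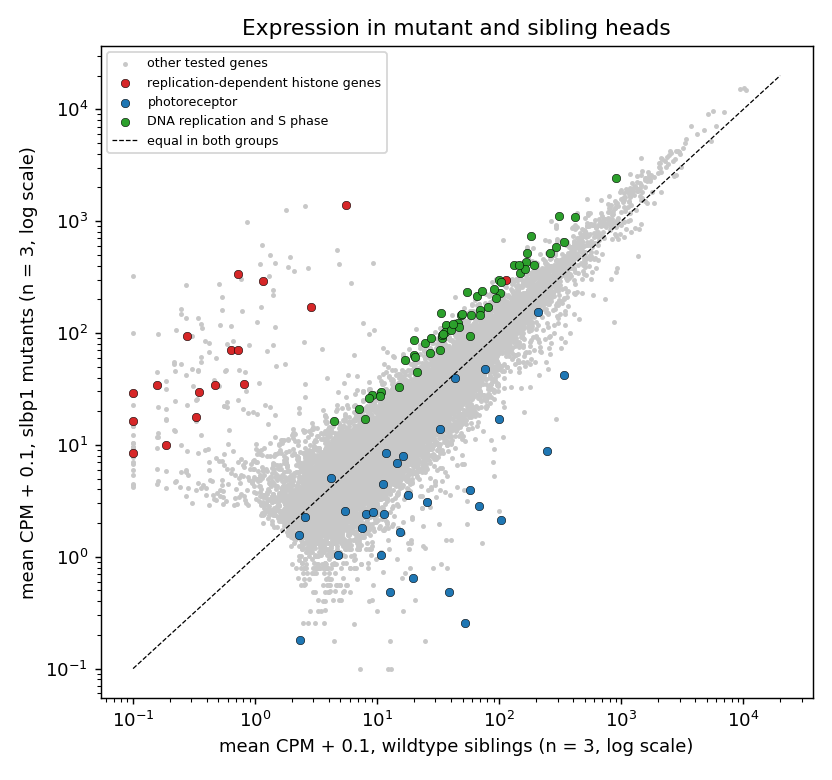
Mean CPM plus 0.1 in 3 sibling libraries (x axis) and 3 mutant libraries (y axis), both on log scales, with 1 point per tested gene; colours mark 3 gene lists and the dashed line marks equal values. All 17 tested replication-dependent histone genes lie above the line, and 24 of 32 photoreceptor genes were called lower.

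Replication-dependent histone genes were higher in mutants without exception among those tested. Most of those tested were near 0 in siblings, so they passed the count filter through the mutants. Without a low-count filter 18 of 19 were called higher. All 17 tested members rose, counted over all genes and also adjusted over the list alone, with a median log2 fold change of 6.83, or 6.66 with the 3 genes at 0 in siblings set to their bound; without any 1 sibling library it was 7.65 to 7.93. The core histone gene hist2h3c rose from 5.46 ± 0.582 to 1397 ± 492 CPM and hist1h2a3 from 1.05 ± 0.438 to 294 ± 66.3 CPM (SD, n = 3). hist2h2l, chosen after its values were seen, rose least, by a log2 fold change of 1.40, from 113 ± 10.1 CPM, and held most of the sibling signal of the list. Summed over 20 genes, the list had 2949 ± 538 CPM in mutants and 125.8 ± 11.2 CPM in siblings. Selection of polyadenylated RNA is not given, and if it was used, these values would not measure all histone mRNA. Camera gave an adjusted p of 1.24e-20 with the preset correlation. With an estimated correlation p = 0.00314 (adjusted p = 0.0943), so that call was lost, and fry gave an adjusted p of 9.84e-05.

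Other histone and chromatin assembly genes moved less. Of 12 tested replication-independent variants 5 rose and 2 fell (6 and 2 adjusted over the list alone), with h2ax up by 2.65 ± 0.25 (SE) on the log2 scale and MACROH2A2 changed by -0.72 ± 0.16. Their camera call (adjusted p = 0.0425) was lost without mutant replicate 3 (0.0892), without sibling replicate 1 (0.0718) or without sibling replicate 3 (0.0901). It was also lost without a low-count filter (0.0552) and with an estimated correlation (adjusted p = 0.557). Fry did not call these variants either (adjusted p = 0.0669). Of 27 histone chaperone and chromatin assembly genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone), among them CHAF1B (1.70), chaf1a (1.64), ASF1B (1.79) and NASP (1.55 on the log2 scale); the faller, NAP1L4, was chosen after its values were seen. The camera adjusted p was 6.09e-06, and adjusted p = 0.356 with an estimated correlation. For histone 3' end processing, 10 of 22 rose and 0 fell (11 and 1 adjusted over the list alone), including LSM11 (1.38), SRRT (0.86) and slbp itself. Its camera adjusted p was 0.000941, and adjusted p = 0.461 with an estimated correlation.

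Cell cycle genes rose together. Of 56 DNA replication and S phase genes 54 rose and 0 fell (55 and 0 adjusted over the list alone), with a median log2 fold change of 1.48. The replication licensing factor CDC6 went from 33.3 ± 6.21 to 150 ± 19.4 CPM (SD, n = 3), and TYMS, the thymidylate synthase gene, from 54.5 ± 7.49 to 231 ± 42.8 CPM, with E2F8 and POLA2 higher by 1.70 and 1.57 on the log2 scale. Of 50 G2 and mitosis genes 45 rose and 0 fell (48 and 0 adjusted over the list alone), with a median of 1.07 and kif20a, CKS1B, BIRC5 and cdca8 in front. Camera adjusted p were 1.91e-25 and 5.02e-18, and adjusted p = 0.356 for each with an estimated correlation.

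Most genes of the DNA damage response were higher, and p53 targets were mixed. Of 37 DNA damage and replication stress genes 28 rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.94, among them the checkpoint kinase gene CHEK1 (1.80), the helicase gene blm (1.64), exo1 (1.49) and HUS1 (1.85). Another of these risers, rad9a, is among the 100 nearest genes on either side of slbp and was chosen after its values were seen. Camera gave an adjusted p of 1.09e-11, and adjusted p = 0.356 with an estimated correlation. Of 31 p53 target and apoptosis genes 10 rose, 3 fell and 18 were not called (11 rose and 3 fell adjusted over the list alone), with a median of 0.32, or 0.07 when scaled by total counts alone. The cell cycle inhibitor gene cdkn1a rose from 3.80 ± 0.140 to 15.8 ± 2.27 CPM (SD, n = 3). mdm2 rose by 1.26 and CCNG1 by 1.73 on the log2 scale, and CCNG1 is among the 100 nearest genes on either side of slbp. The fallers included bcl2l10 and RRM2B, chosen after their values were seen. The camera call on this list (adjusted p = 0.0304) was lost without mutant replicate 2 (0.0644) and without a low-count filter (0.0552). With an estimated correlation the camera adjusted p was 0.342, while fry gave an adjusted p of 0.00223 for a rise.

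Photoreceptor genes were lower, with 24 of 32 tested members called lower and 0 higher (27 and 0 adjusted over the list alone). Their median was -2.29, and -1.61 without mutant replicate 2 or -1.48 without a low-count filter. The photoreceptor transcription factor crx fell from 244 ± 45.6 to 8.65 ± 3.83 CPM, PRDM1 from 68.0 ± 6.06 to 2.77 ± 1.48 CPM, and NEUROD1 from 339 ± 50.5 to 42.4 ± 8.01 CPM (SD, n = 3). Camera gave an adjusted p of 9.5e-14, and adjusted p = 0.218 with an estimated correlation.

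Neuronal lists were lower as well. Of 52 neuron and synapse genes 43 fell and 1 rose (44 and 1 adjusted over the list alone), with a median of -1.45. GNG3, a G protein subunit gene, fell from 145 ± 26.5 to 44.6 ± 8.83 CPM and sncb, a synuclein gene, from 237 ± 26.0 to 87.4 ± 10.5 CPM (SD, n = 3). The riser was STMN1 (ENSDARG00000004169), up by 1.79. It was matched to the list member stmn1b only by its upper-case symbol, so it may be another copy. In the amacrine, horizontal and bipolar list 18 of 29 fell and 2 rose (19 and 2 adjusted over the list alone), including VSX1, BHLHE23, TFAP2A and TFAP2C, with a median of -1.47. Its risers were SLC6A9 and BHLHE22, and that of the ganglion cell list SNCG (ENSDARG00000034423), all chosen after their values were seen. In the retinal ganglion cell list 18 of 29 fell and 1 rose (22 and 2 adjusted over the list alone), with POU4F2 at -3.68, ISL1 at -1.74 and a median of -1.03. The camera adjusted p were 5.51e-16, 4.75e-07 and 2.57e-07 in that order, and adjusted p = 0.356 for each with an estimated correlation.

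Progenitor genes moved the other way or were mixed. Of 30 neural progenitor and Notch pathway genes 13 rose and 1 fell (17 and 2 adjusted over the list alone). Their median was 0.58, or 0.31 when scaled by total counts alone. her2 rose by 2.24 and SOX3, ID1 and sox19a by 1.46, 1.15 and 1.08 on the log2 scale, and the faller, chosen after its values were seen, was SOX1. Camera gave an adjusted p of 0.00104, and adjusted p = 0.342 with an estimated correlation. The retinal progenitor and ciliary margin list was not called (adjusted p = 0.355 by camera, median 0.26), with 8 of 27 higher and 5 lower (8 and 7 adjusted over the list alone). The retinal homeobox gene rx1 rose from 35.0 ± 5.998 to 82.7 ± 10.97 CPM (SD, n = 3), and HES1 and CCND1 rose by 1.06 and 1.39 on the log2 scale. The proneural list was mixed and not called (adjusted p = 0.279 by camera), with 6 of 36 higher and 11 lower (7 and 11 adjusted over the list alone): ascl1a rose by 1.73, and NEUROD6 (ENSDARG00000020794) changed by -3.04.

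**Figure D2:**
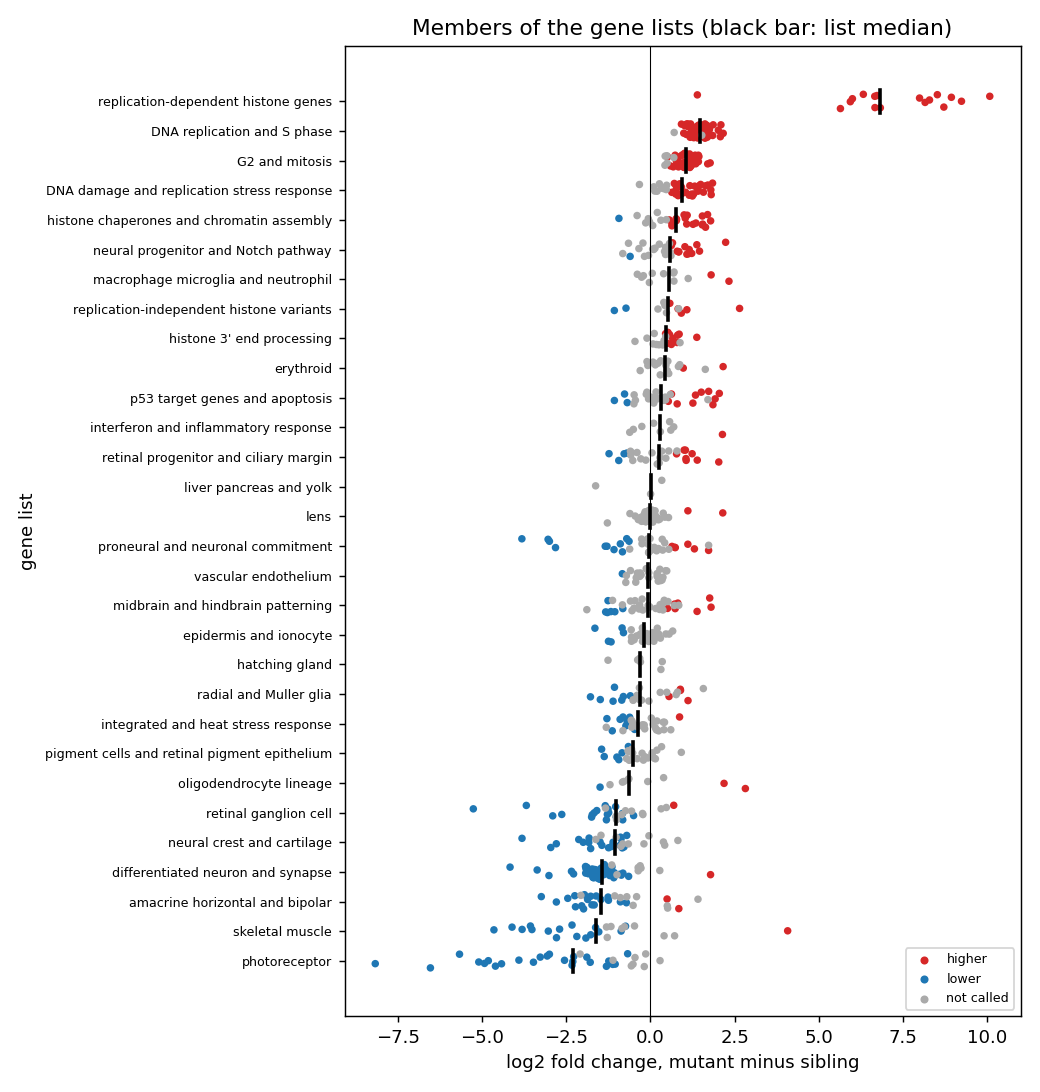
Log2 fold change, mutant minus sibling, of each tested member (points) of 30 gene lists, ordered by list median (black bars); red and blue points were called higher and lower. The histone list has a median of 6.83 and the photoreceptor list one of -2.29; without mutant replicate 1 or 2, or without a low-count filter, the skeletal muscle list has a lower median than the photoreceptor list.

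Outside the nervous system, most cartilage and muscle genes were lower, and a minority of pigment genes. Of 30 neural crest and cartilage genes 19 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.06. The cartilage collagen gene col9a3 fell from 241 ± 36.7 to 55.3 ± 14.8 CPM (SD, n = 3) and the matrix gene MATN4 changed by -1.99 on the log2 scale. Of 25 skeletal muscle genes 16 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -1.63, the riser being nebl, chosen after its values were seen. The calcium pump gene atp2a1 had 18.8 ± 7.39 CPM in siblings and 1.31 ± 0.877 in mutants, and MYOG changed by -2.33. Of 26 pigment cell and retinal pigment epithelium genes 6 fell and 0 rose (4 and 0 adjusted over the list alone), including TYRP1 (-1.37), RPE65 (-1.45) and pmelb (-0.99). Camera adjusted p were 1.5e-07, 1.51e-07 and 0.0152 in that order, and adjusted p = 0.356, 0.342 and 0.411 with an estimated correlation. The pigment call was lost without sibling replicate 3 (adjusted p = 0.0552 by camera).

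The other lists were not called by camera. Lens genes had a median log2 fold change of -0.02, with 2 of 39 higher, and vascular endothelium -0.06, with 1 of 24 lower. Erythroid genes had a median of 0.45 (2 of 18 higher), macrophage, microglia and neutrophil genes 0.54 (2 of 12 higher), and interferon and inflammatory genes 0.30 (1 of 9 higher). Epidermis and ionocyte genes had a median of -0.20 (5 of 31 lower), 6 hatching gland genes one of -0.30 and 3 liver, pancreas and yolk genes one of 0.01. The integrated and heat stress list had 1 gene higher, PSAT1, and 8 of 29 lower, including the chaperone gene HSPA5. Midbrain and hindbrain patterning genes went both ways (7 higher and 6 lower of 35), with otx2a and ZIC2 (ENSDARG00000037178) higher and GATA3 and MEIS2 (ENSDARG00000098240) lower. Radial and Muller glia genes were also split (4 higher and 7 lower of 23), with GFAP higher and SLC1A2 (ENSDARG00000102453) lower, and 10 oligodendrocyte lineage genes had 2 higher and 1, SOX10, lower.

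**Figure D3:**
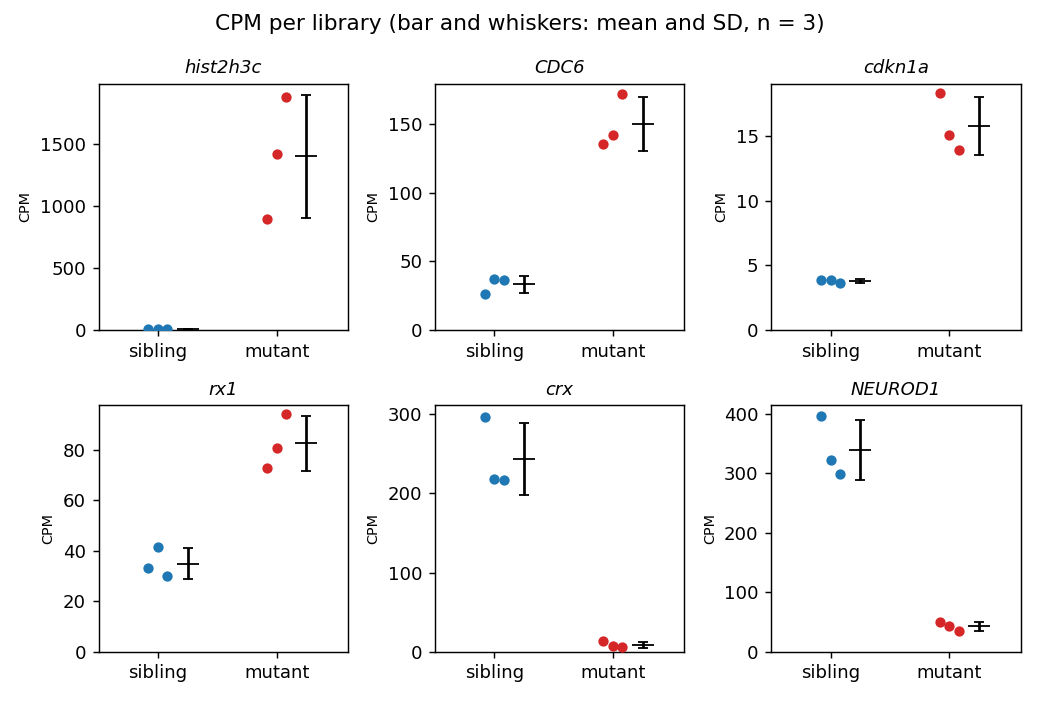
CPM of 6 genes in each sibling (blue) and mutant (red) library, with the mean and SD of 3 libraries as black bars. hist2h3c, CDC6, cdkn1a and rx1 lie higher in every mutant library than in any sibling, and crx and NEUROD1 lie lower.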

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

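Chosen after seeing the data were the tests without histones and their neighbours and with clone-named neighbours added to the histones. Over RLE and upper quartile factors, total counts alone, 2 other filters, DESeq2 and limma-voom, between 3879 and 4555 genes were called, with 0 calls shared with the reported ones changing sign. Higher calls dropped to 1095 with total counts alone, where the median of all genes moved to -0.26. A threshold of 0.01 left 2052 genes and glmTreat against a fold of 1.5 left 1622, both by construction stricter. Removing the abundant lists left 4026 genes and removing histones and neighbours 3964. Leaving out 1 library gave 2521 to 3763 genes, 1158 to 1811 of them lower and 1363 to 1952 higher, with fewer samples as the construction, and the smallest values came without sibling replicate 1. The slbp transcript was called higher, by 0.54 to 0.91, with each of these size factors, filters and tools, with each library left out and with the replicate block; glmTreat was read only as a count. In those fits 17 or 18 histone genes were called, all that were tested except without a filter (18 of 19), and 48 with clone-named neighbours added. Camera called 15 to 17 lists in the alternative fits (it was not run for DESeq2). Fry called 15, which are the lists that camera called in the main fit except the replication-independent variants. Camera with an estimated correlation called 0, with 3 lists (histones, photoreceptor, neural progenitor) at an unadjusted p under 0.05. Of 116 named genes, all called, 16 lost the call in 1 or more alternatives and 0 reversed. With the replicate number as a block 5059 genes were called. The labels state no pairing, so the numbers were not taken as pairs in the main fit. Residuals of same-numbered libraries correlated at 0.24, 0.09 and 0.18. Across the groups each library correlated best with its own number, a hint of pairing from the data alone. Calls by chromosome were not run, as no chromosomes of the same build were used here, and histones were already taken by symbols only. Depth limits genes under about 0.7 CPM.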

Other observations

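Tests of the histone pattern, of less neural tissue, of slower development and of the splits, the gene lists of germ plasm and of the piRNA pathway and meiosis, and the histone neighbours were chosen only after results were seen. Short clone-named genes next to the named histone genes, in the GRCz12tu gene order, had the same direction. All 31 tested of 40 such neighbours were higher in mutants. Their median log2 fold change was 8.07, or 7.55 with the 7 genes at 0 in siblings set to their bound. Most of the 31 were near 0 in siblings, so they passed the count filter through the mutants. Summed, the 40 neighbours had 4454 ± 1320 CPM in mutants and 16.5 ± 4.03 CPM in siblings (SD, n = 3). They carry no histone name in the tables used here.

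Several genes of the piRNA pathway and meiosis were higher in mutant heads. Of 40 genes, 12 had enough counts to test with edgeR, and 9 of these were called higher and 0 lower (9 and 0 adjusted over the list alone), with a median log2 fold change of 3.66, or 2.75 with 2 genes set to their bound. PIWIL1, a Piwi protein gene of the germ line, had 46.3 ± 10.2 CPM in mutants and 0.480 ± 0.462 in siblings (SD, n = 3), and gtsf1 had 35.3 ± 5.39 against 5.24 ± 1.21. TDRD1 and the meiotic cohesin gene stag3 had no count in siblings and were at least 6.90-fold and 6.65-fold higher, while prdm9 and tdrkh had log2 fold changes of 0.02 and 0.06. Most called members were near 0 in siblings, so they passed the count filter through the mutants, and no set test was run. Of the 28 untested genes 17 had a higher mean CPM in mutants, such as SYCP3 (38 counts against 6) and PIWIL2 (31 against 5), 8 had a lower one, such as SYCP1 (7 against 18) and YTHDC2 (14 against 34), and 3 had no count.

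Histone genes were far higher in the mutant libraries. Scaling does not account for it: the median log2 fold change of the list was at least 6.54 under the 4 scalings run, total counts alone included. Capture of polyadenylated RNA, which leaves out stem-loop mRNA in siblings, may account for the low sibling level: the summed CPM of the list in siblings was 1.38% of that of the replication-independent variants (1.48% without the 2 H2AX genes, whose mRNA is known in both forms). RNA selection is not given in the labels, and the bound was set after the values were seen. Genes with names of small non-polyadenylated RNA held 0.002% to 0.0091% of the counts per library. This low share goes with such capture but does not settle it, as the treatment of reads that map to several genes is not given either. Whether mutants hold more histone mRNA, or more of it with a poly(A) tail, stays open.

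Photoreceptor and neuron genes were lower while S phase genes were higher, a pattern worded in this way after results were seen. Less neural tissue in the mutant dissections could be the whole cause of the first part. It would then lower progenitor genes about as far as neuron genes (median -1.45). The medians of the retinal and neural progenitor lists were 0.26 (SD over members 0.83) and 0.58 (0.69), which goes against it as the whole cause. The bound first set, a called rise of the retinal list, was not met. Comparison with the neuron list was added as a bound only after these values were seen, so it is no independent test. The SD over genes does not measure error between libraries. Slower development of the whole head may account for both parts: 4 of 4 lists taken as differentiated non-neural tissue had a median below 0. The neural crest and cartilage list among them also holds genes of the neural crest itself, such as TFAP2A (-1.77) and SOX10 (-1.49 on the log2 scale). Its fall was therefore not limited to genes of differentiated tissue, which weakens its use in this test. Lens was only at -0.02, with a mean of 0.04 and with 2 of 39 genes called higher and 0 lower. The erythroid and macrophage lists, outside that test, had medians of 0.45 and 0.54. None of these 3 lists was called. This test was set when single genes but no list medians had been seen, and a count of called lists, also tried, gave 3 of 4 lower, with these calls lost with an estimated correlation (adjusted p = 0.356, 0.342 and 0.411). No staged siblings were analysed here, so an effect of the genotype on these tissues themselves stays open.

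The higher level of these piRNA and meiosis genes could come from germ cells in the mutant dissections. Only 1 of 13 germ plasm genes, TDRD7, had enough counts to test, with a log2 fold change of -1.01, and although this value met the bound that had been set against germ cells before it was seen, 1 gene was judged, once this was seen, too few to decide. DDX4 (48 counts in mutants against 3 in siblings), gra (24 against 6), rgs14a (16 against 6) and buc (7 against 0) had more counts in mutants, NANOS3 had 10 against 6, DAZL and ca15b had 0 in every library, and the list without DDX4 summed to 189 against 295, of which TDRD7 gave 111 and 260, or to 78 against 35 without TDRD7 as well. As for a haplotype linked to slbp, 0 of the 8 called members placed in the gene order were among the 100 nearest genes on either side of slbp. This goes against differences within that window as the cause for these members as a group. The test does not cover linked genes farther along the chromosome, where calls were not compared, or effects of a linked variant on genes elsewhere.

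Of 199 tested genes within 100 genes on either side of slbp, 53 (26.6%) were called, against 2750 of 10960 others (25.1%), an odds ratio of 1.08 (95% interval 0.774 to 1.5, two-sided Fisher's exact test, p = 0.621). The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4004 genes by edgeR's quasi-likelihood test, and 1 split gave as many (the real one). The highest of the others called 0, with at most 380 genes at an unadjusted p under 0.05 by that test. Those splits mix mutants and siblings in both groups, which widens the spread within groups, so their 0 calls are no measure of chance.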
